A study of Arabidopsis thaliana with 37 samples.

How the data were processed

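Total RNA from 37 samples of an Arabidopsis suspension culture was measured, with 1 single-channel oligonucleotide array of 22810 probe sets per sample, 64 of them controls. The deposited values are MAS5 signal intensity, 1 value per probe set and array, scaled to a common trimmed mean, per the submitters' processing notes and the labels. The MAS5 version and other settings are not given in the sources used here. Raw probe-level files were not used here.

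Groups were formed from sample titles and the series description. For 4 groups another label field names a different compound, and the title was used. Those arrays were compared with the arrays of the other compound as a check. The labels do not say that replicate numbers mark a shared batch, and they do not say whether replicates were separate cultures.

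Each array was scaled to a common 2% trimmed mean, which was already 500.04 on each array with a largest deviation of 0.009, so this step changed nothing. Values were taken as log2 of the signal plus 21.3, the 25th percentile of all signals. Probe sets were tested if at least 2 arrays reached 149.4, the median of all signals, which left 13381 of 22746. No pair of arrays held identical values, and the largest share of equal values between a pair was 0.452%. The trimmed mean fixes signal over background on each array at a common level, and small changes near the pseudocount are compressed.

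A linear model with 1 mean per group was fitted to all 37 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend in the variance), with 19 residual and 10.4 prior degrees of freedom. Standard errors are the moderated ones of this fit. Tests were 2-sided, p-values were adjusted within each comparison over all tested probe sets by the Benjamini-Hochberg method, and the threshold was an adjusted p under 0.05. Each treatment was compared with untreated cells of its own time. Doses, times, pairs of treatments and the difference of effects between times were tested as contrasts of the same fit.

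Gene lists were tested with camera in limma, with a preset correlation of 0.01 between members and, beside it, an estimated one, and adjusted over the lists of each comparison. Of 24 lists fixed before the data were examined, 19 had at least 3 measured members and were tested; 11 further lists were chosen after seeing the data and adjusted separately. For each list the members past the threshold were counted with p-values adjusted over all probe sets and adjusted over the list alone. The comparisons, the threshold, the rule for naming genes and the first set of alternatives were also chosen before the data were examined.

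Gene names came from a probe table that gave 1 symbol or locus code for 13513 probe sets, several for 503 and none for 8730. Of the tested probe sets, 7347 stood for 1 gene each, 7265 genes in all. Probe sets for AOX1A and NDA1 carry no gene name there, so these genes were not analysed here. In lists, the probe set with the highest mean stood for its gene. Some genes belong to several lists, so list results are not independent of each other. NDB2 is in alternative respiration and the mitochondrial dysfunction stimulon, and AT5G51440 is in that stimulon and the heat shock list.

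Genes were named by rule: in each treatment the 6 largest rises and 6 largest falls, up to 5 members of each list the comparison asked about (or the 2 largest differences where none passed) and up to 3 of each other list past the threshold. In direct, dose and time comparisons these numbers were 4, 4, 3 and 2. Named genes had to pass the threshold, carry 1 gene name and have every array of the first group beyond every array of the second, which was not required of differences between effects. NDB2 and NDB4 were followed in every treatment. Names given in brackets and the functions of genes are general background.

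Mannitol, with 1 array, was not tested. Probe sets beyond all 4 untreated arrays and at least 2-fold from their mean were counted, and list medians were placed among 10000 random lists of equal size and signal level.

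The fit was tested on simulated data with the real group sizes. In a simulated comparison of chitin with untreated cells over 13381 probe sets, 26 of 50 probe sets changed 1.5-fold were called, 44 of 50 changed 2-fold and 50 of 50 changed 3-fold, with 4% of calls false. In a simulated comparison of norflurazon with untreated cells the counts were 28, 44 and 50, with 5% of calls false. Noise was drawn independently for each array, with the same spread in every group. Links between replicates, as found below among the 12 h arrays, were not simulated, so these shares do not cover them.

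Alternatives were quantile normalization, values as deposited, no pseudocount, a pseudocount at the median, no filter, a filter for mean levels above their median, eBayes without trend, a replicate block, an estimated correlation, only the arrays of the groups compared, and each array left out in turn. A further 4 were chosen after seeing the data: untreated 3 h arrays 1 and 2 alone, arrays 3 and 4 alone, arrays of 1 time point alone, and a replicate block among the 12 h arrays. Only the untreated 3 h group holds replicates 3 and 4. In comparisons with that group the replicate block thus leaves its arrays 1 and 2 as the controls. As a check on the replicate block, differences between replicates 1 and 2 were correlated across 136 pairs of groups. Of 66 pairs of 3 h groups 3 lay above 0.1 (-0.165 to 0.128), and of 60 pairs across times 0 did. All 10 pairs of 12 h groups did (0.109 to 0.441, the highest for chloramphenicol with cysteine and the next 0.215). Replicate numbers thus tie the 12 h samples together, by the data and not by the labels. The fit planned beforehand holds no block, and the block among the 12 h arrays was run beside it. Figures and preparation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.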

Results

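Transcript levels were measured in a wild-type Arabidopsis thaliana suspension cell culture, pale green in colour, on 37 single-channel oligonucleotide arrays, with 1 array per sample. The culture was left untreated or exposed to 1 of 12 chemical, elicitor, temperature or gas conditions for 3 h, which gave 27 arrays in 13 groups, or to 1 of 4 compounds for 12 h, which gave 10 arrays in 5 groups with their own untreated arrays. The untreated 3 h group held 4 arrays, the mannitol group 1 and each of the other 16 groups 2. The number of arrays limits the precision of every value. The labels do not say whether replicates came from separate cultures, so each p-value measures only the spread between these samples.

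Each value below is a log2 difference with its standard error from the fit, against 4 untreated arrays at 3 h or 2 at 12 h unless another group is named. Genes named as risen or fallen had every array of the first group beyond every array of the second, except in the comparisons of effects between times, where this was not required. For AT1G53540, AT2G43620, UGT76B1, GSTU25, GH3.3, AT1G76360 and GAT1_2.1 the lower group's mean signal in a comparison below lay under the pseudocount of 21.3, so the size of those differences depends on the pseudocount. Of 22746 probe sets that are not controls, 13381 were tested. The median of all tested probe sets lay off 0 by more than 0.1 in flagellen-treated cells (-0.165), in cells under N2 (-0.101), between flagellen and chloramphenicol (-0.143) and between chitin and flagellen (0.12), and changes there stand relative to those shifts. The lists for glycolysis, antioxidant enzymes and the unfolded protein response passed the camera list test in 0 of the 15 treatments. Only 6 of 18, 5 of 25 and 3 of 16 of their genes were measured, so this says little about those pathways. Members counted below are the measured ones. These were 4 of 29 listed genes for xenobiotic detoxification and 6 of 31 for pattern-triggered immunity. They were 5 of 16 for the mitochondrial dysfunction stimulon and 8 of 26 for the hypoxia response. Sulfur assimilation had 5 of 31 measured, heat shock and chaperones 4 of 21 and cell division 3 of 28. Carbon starvation had 7 of 23, cold response 7 of 22 and alternative respiration 4 of 17. Carotenoid and tetrapyrrole synthesis had 3 of 21 and photosynthesis 4 of 33. Results of these lists cover the measured members and not whole pathways.

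**Figure D1:**
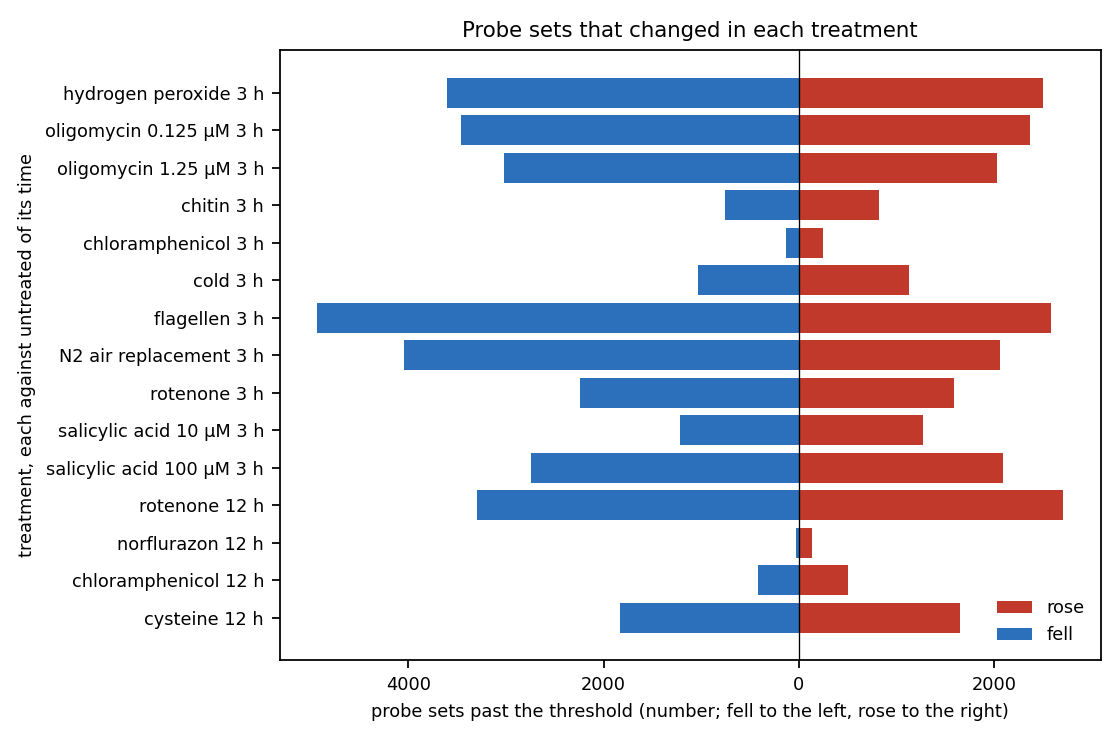
Number of probe sets past the threshold in each of 15 treatments against untreated cells of its time, with those that rose to the right of 0 and those that fell to the left. The counts range from 163 for norflurazon to 7520 for flagellen.

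Hydrogen peroxide, an oxidant, was applied at 10 mM for 3 h, and the question was which transcripts respond to oxidative stress. The transcript of the small heat shock protein AT1G53540 (HSP17.6C) rose by 7.60 ± 0.29 (SE, n = 2 treated arrays, adjusted p = 9.95e-19), and that of AT2G29500 (HSP17.6B) by 5.85 ± 0.23. All 4 measured members of the heat shock and chaperones list rose (median 5.24, adjusted p = 2.41e-07), as did all 4 of xenobiotic detoxification (median 4.26, adjusted p = 6.57e-07), among them the glycosyltransferase gene UGT73B4 at 4.61 ± 0.20. In the mitochondrial dysfunction stimulon, a group of nuclear genes known to answer mitochondrial stress, 4 of 5 members rose (median 2.46, adjusted p = 1.35e-05), including the alternative NAD(P)H dehydrogenase gene NDB2 at 2.46 ± 0.15. Sulfur assimilation followed with 4 of 5 risen, led by the beta-glucosidase gene BGLU28 at 4.29 ± 0.22 (adjusted p of the list = 0.000552). All 3 members of carotenoid and tetrapyrrole synthesis fell, such as PORB, a protochlorophyllide reductase gene, at -1.80 ± 0.18 (adjusted p of the list = 0.0117). Adjusted over the list alone, these counts were identical. Of 67 plastid-encoded transcripts, 43 fell and 1 rose (median -1.24, adjusted p = 1.21e-11), with psaA, a photosystem I gene, at -3.50 ± 0.34; adjusted over the list alone, 46 fell. That call was lost at adjusted p = 0.195 with an estimated correlation between members. The actin 3'/5' signal ratios of these arrays (mean 2.06) both lay above the 1.55 to 1.91 of the untreated 3 h arrays, and 1 of their GAPDH ratios, 1.14, lay above all 4 as well. In total 2505 probe sets rose and 3600 fell.

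Oligomycin, an inhibitor of the mitochondrial ATP synthase, was added at 0.125 or 1.25 µM for 3 h. The transcript of AT3G15450 (SEN5), known as a gene of sugar starvation, rose by 5.06 ± 0.20 at the lower dose (n = 2, adjusted p = 3.62e-18) and by 4.78 ± 0.20 at the higher (n = 2). The carbon starvation list rose at both doses, with 6 and 5 of 7 members up and medians of 1.73 (adjusted p = 7.82e-07) and 1.77 (adjusted p = 1.59e-07). Its members included ATG8E, an autophagy gene, at 2.76 ± 0.14 and 2.59 ± 0.14, and IVD, whose product degrades branched-chain amino acids, at 2.03 ± 0.12 and 1.78 ± 0.12. In xenobiotic detoxification, 3 of 4 members rose at each dose, UGT73B4 by 3.54 ± 0.20 and 2.67 ± 0.20 (adjusted p of the list = 9.36e-05 and 0.000173). Adjusted over the list alone, 6 of the carbon starvation list and 4 of xenobiotic detoxification rose at each dose.

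All 14 mitochondrially encoded transcripts rose at both oligomycin doses, adjusted over the list alone as well, with medians of 1.16 and 1.37. The complex I transcript nad1 rose by 1.57 ± 0.21 at the lower dose and nad9 by 1.64 ± 0.21 at the higher. The list passed at the lower dose (adjusted p = 7.82e-07) but not with an estimated correlation (adjusted p = 0.0781 with an estimated correlation), and passed both ways at the higher dose (adjusted p = 5.65e-09). On the same 4 arrays the 25S ribosomal RNA control probe set read 14770 to 17327, against 207 to 497 on the untreated 3 h arrays. At the lower dose 2368 probe sets rose and 3464 fell, and at the higher dose 2033 and 3016. No vehicle control for the ethanol in which oligomycin was dissolved is named in the labels, so the untreated arrays served for both doses.

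**Figure D2:**
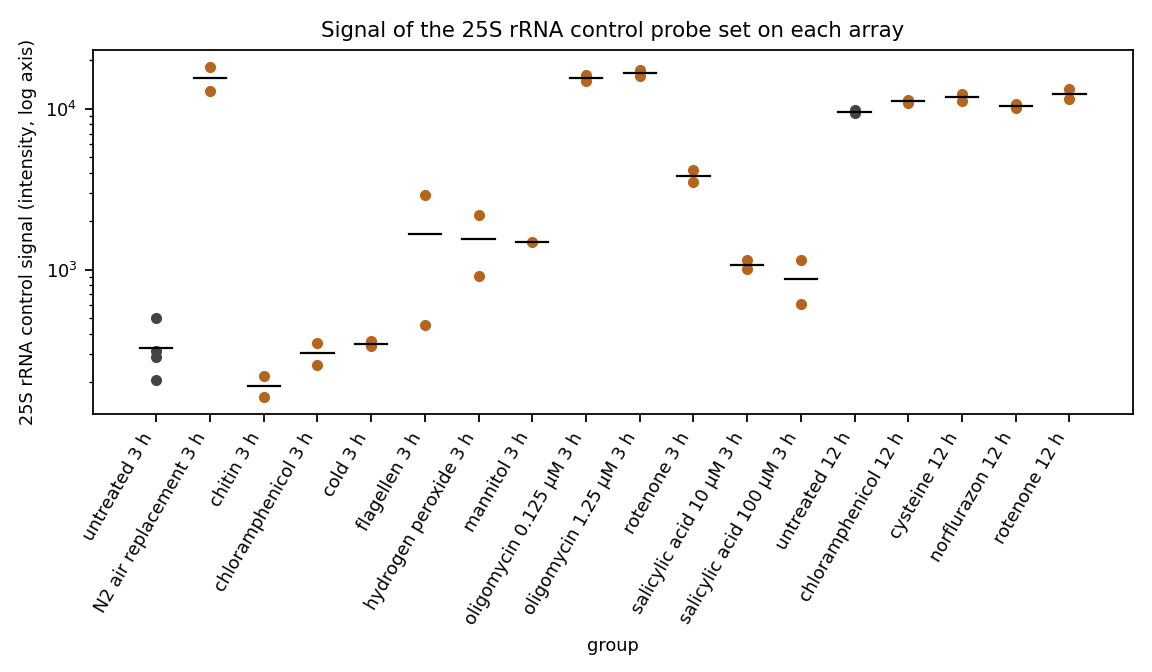
Signal (intensity, log axis) of the 25S ribosomal RNA control probe set on each of the 37 arrays, with dots for arrays and lines for group means. The oligomycin and N2 arrays read 12953 or more and the untreated 3 h arrays 497 or less.

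Chitin, a fungal cell wall polymer that plant cells sense as an elicitor, was given at 50 mg/L for 3 h. Transcripts of AT2G43620 and AT3G46280 rose by 5.67 ± 0.38 and 4.99 ± 0.24 (n = 2, adjusted p = 3.15e-12 and 2.71e-15). In the pattern-triggered immunity list, 5 of 6 members rose, adjusted over the list alone as well (median 1.69, adjusted p = 8.42e-08), among them the transcription factor gene WRKY22 at 2.46 ± 0.34 and the ubiquitin ligase gene PUB22 at 2.43 ± 0.28. The dehydrin gene COR47 fell by 2.31 ± 0.16. The count past the threshold was 1575, of which 823 rose and 752 fell, and it was 834 without chitin replicate 1 and 954 without chitin replicate 2.

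Flagellen, spelled so in the labels and read here as the bacterial elicitor flagellin, was given at 1 µM for 3 h. Transcripts of AT2G43620, AT2G38870 and AT3G46280 rose by 7.87 ± 0.38, 7.35 ± 0.35 and 7.13 ± 0.24 (n = 2, adjusted p = 6.74e-17, 5.85e-17 and 2.85e-20). All 6 members of pattern-triggered immunity rose, adjusted over the list alone as well (median 2.09, adjusted p = 1.55e-05). PUB22 rose by 5.59 ± 0.28, WRKY22 by 4.88 ± 0.34 and the immune signalling kinase gene BIK1 by 1.29 ± 0.11. GH3.3, an auxin-conjugating enzyme gene, fell by 3.88 ± 0.27. Of 67 plastid-encoded transcripts, 33 rose and 3 fell, adjusted over the list alone as well (median 0.43, adjusted p = 0.000134; adjusted p = 0.519 with an estimated correlation). Probe sets past the threshold numbered 7520, with 2583 up and 4937 down.

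Set directly against flagellen, chitin gave lower levels of 4 of the 6 immunity genes, with 1 also higher adjusted over the list alone (median -1.36, adjusted p = 0.00147), although that list call was lost with an estimated correlation (adjusted p = 0.122 with an estimated correlation). PUB22 stood lower after chitin by a log2 difference of -3.16 ± 0.32 (n = 2 and 2, adjusted p = 4.85e-09), WRKY22 by -2.43 ± 0.39 and PUB23 by -1.62 ± 0.26. GH3.3 stood higher by 4.24 ± 0.31. Of the probe sets tested, 3214 were higher and 1751 lower after chitin. The doses, 50 mg/L and 1 µM, are not matched.

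Cold, at 10 °C for 3 h, raised transcripts of the dehydrin gene LTI30 by 2.82 ± 0.14 (n = 2, adjusted p = 4.82e-15) and of the zinc finger gene STZ (ZAT10) by 2.33 ± 0.18. In the cold response list 5 of 7 members rose, adjusted over the list alone as well (median 1.39, adjusted p = 4.56e-11), including COR27 at 1.53 ± 0.12 and COR47 at 1.27 ± 0.16. Hypoxia response genes moved down: 6 of 8 members fell and 0 rose (median -1.46, adjusted p = 8.08e-11; 7 fell adjusted over the list alone). AT4G10270 (WIP4) fell by 5.36 ± 0.19, AT3G10040 (HRA1) by 4.43 ± 0.33 and the calcium sensor gene CML38 by 2.31 ± 0.22. The actin 3'/5' signal ratios of the cold arrays, 2.46 and 2.12, lay above the 1.55 to 1.91 of the untreated 3 h arrays, and both of their GAPDH ratios (mean 1.11) lay above all 4 as well (highest 1.09). Of 2159 probe sets past the threshold, 1127 rose and 1032 fell; the count was 804 without cold replicate 2, 1235 with only the arrays compared in the fit and 1378 against untreated arrays 3 and 4 alone.

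Replacement of air by N2 for 3 h asked how the cells respond to low oxygen. CML38 rose by 2.59 ± 0.22 (n = 2, adjusted p = 8.28e-11) and AT3G10020 (HUP26) by 0.81 ± 0.12, yet the hypoxia response list as a whole did not pass (3 of 8 rose and 1 fell, median 0.01, adjusted p = 0.172). The hypoxia response passed with untreated 3 h arrays 1 and 2 alone (median 0.36). A replicate block leaves the same arrays as controls here and is no separate check (median 0.36, adjusted p = 0.0214). In xenobiotic detoxification all 4 members rose (median 2.18, adjusted p = 4.12e-05), with UGT73B4 at 2.53 ± 0.20, and in carbon starvation 5 of 7 (adjusted p = 4.12e-05), with AT3G15450 at 4.26 ± 0.20. Of the heat shock and chaperones list, 3 of 4 rose, among them AT5G51440 (HSP23.5, a mitochondrial small heat shock protein) at 3.97 ± 0.25 (adjusted p of the list = 0.0027). These counts were identical adjusted over the list alone. Probe sets past the threshold numbered 6105, of which 2063 rose and 4042 fell.

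The organelle transcripts moved apart under N2. Of 14 mitochondrially encoded transcripts 9 rose (median 0.78, adjusted p = 0.000685; adjusted p = 0.254 with an estimated correlation), led by nad1 at 1.91 ± 0.21. Of 67 plastid-encoded transcripts 34 fell and 0 rose, 35 adjusted over the list alone (median -0.55, adjusted p = 0.000685; adjusted p = 0.528 with an estimated correlation), and rbcL, the gene of the large subunit of Rubisco, fell by 1.93 ± 0.20. Without N2 replicate 1 the plastid list no longer passed (median -0.28, adjusted p = 0.251). The 25S ribosomal RNA control read 12953 and 18216 on the N2 arrays.

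Rotenone, an inhibitor of respiratory complex I, was given at 40 µM for 3 h or 12 h. At 3 h, BGLU28 rose by 5.18 ± 0.22 (n = 2, adjusted p = 1.77e-17) and UGT73B4 by 4.74 ± 0.20. NDB2, whose product can bypass complex I, rose by 1.55 ± 0.15, while NDB4 differed by 0.24 ± 0.17 (adjusted p = 0.305). All 4 members of xenobiotic detoxification rose (median 3.20, adjusted p = 4.26e-08), 4 of 5 of sulfur assimilation (median 1.45, adjusted p = 9.94e-07) and 4 of 5 of the mitochondrial dysfunction stimulon (median 1.44, adjusted p = 0.000253). These counts were identical adjusted over the list alone. AT3G10040 (HRA1) fell by 3.19 ± 0.33 and the expansin-like gene EXLA3 by 2.40 ± 0.20. Of 3835 probe sets past the threshold, 1593 rose and 2242 fell, with 2424 past it without rotenone 3 h replicate 1.

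After 12 h of rotenone, UGT73B4 rose by 5.48 ± 0.23 (n = 2 and 2, adjusted p = 6.49e-18), the glutathione transferase gene GSTU25 by 4.58 ± 0.40 and AT2G21640 (UPOX) by 4.04 ± 0.22. All 5 members of the mitochondrial dysfunction stimulon rose (median 2.38, adjusted p = 6.17e-06), as did 4 of 4 of xenobiotic detoxification (median 4.16, adjusted p = 1.92e-06) and 6 of 7 of carbon starvation (median 0.99, adjusted p = 2.84e-05). NDB2 rose by 2.38 ± 0.17 and NDB4 by 1.43 ± 0.19. All 3 measured cell division genes fell (median -1.90, adjusted p = 0.000364): PRL (MCM7), a subunit of the replicative helicase, by 1.96 ± 0.13, and the Aurora kinase genes AUR2 and AUR1 by 1.90 ± 0.13 and 1.44 ± 0.14. These counts were identical adjusted over the list alone. The largest falls among named genes were AT4G24780 at -6.20 ± 0.18, PR-1-LIKE at -6.02 ± 0.12 and the expansin gene EXPA4 at -5.43 ± 0.13. In total 2713 probe sets rose and 3294 fell.

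The rotenone effect at 12 h differed from that at 3 h for 2354 probe sets, with 1009 more positive and 1345 more negative at 12 h. The 12 h effect was higher for the mitochondrial dysfunction stimulon (4 of 5 members, median 1.31, adjusted p = 0.00023), with AT2G21640 higher by 2.71 ± 0.29 (n = 2 per treated group), and lower for all 3 cell division genes (median -1.15, adjusted p = 0.00023). It was also lower for EXPA4, by a log2 difference of -5.27 ± 0.17. The carbon starvation list was higher in 5 of 7 members, 6 adjusted over the list alone (median 0.88, adjusted p = 0.00023). Because times and array batches coincide, each effect was taken against untreated cells of its own time. That does not remove a processing difference in the size of effects. The highest signal averaged 19316.5 on 12 h arrays and 26665.4 on 3 h arrays. Time and array processing thus cannot be separated in differences of effects.

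**Figure D3:**
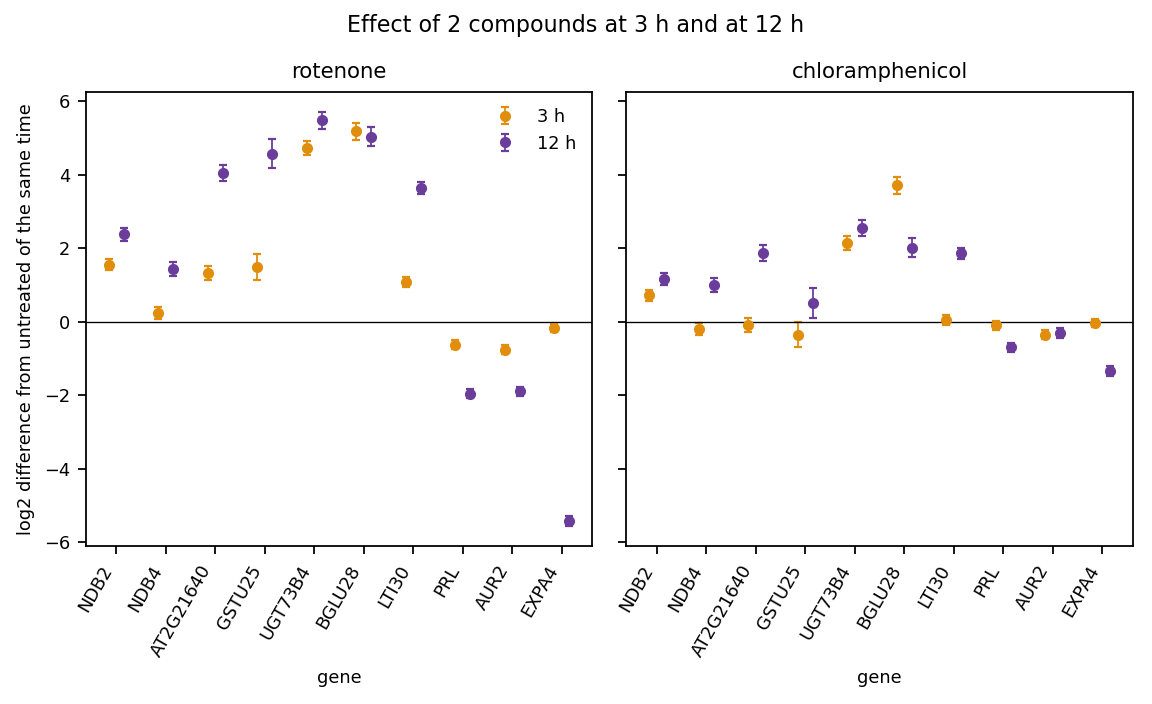
Log2 difference from untreated cells of the same time for 10 genes after rotenone (left) and chloramphenicol (right), with dots for 3 h and 12 h and bars for the standard error of the fit. After rotenone, AT2G21640 lies at 1.33 at 3 h and 4.04 at 12 h, and EXPA4 at -5.43 at 12 h.

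Rotenone and oligomycin, which act on different complexes of mitochondrial respiration, were compared directly at 3 h. The sulfur assimilation list stood higher after rotenone in 4 of 5 members (median 1.82, adjusted p = 3.72e-08), with BGLU28 higher by 5.15 ± 0.26 (n = 2 and 2, adjusted p = 3.08e-15). Carbon starvation stood lower in 5 of 7 (median -1.07, adjusted p = 2.00e-06), with AT3G15450 at -2.64 ± 0.23. Mitochondrially encoded transcripts stood lower in 11 of 14 (median -1.25, adjusted p = 1.28e-08; 12 adjusted over the list alone), with nad1 at -1.93 ± 0.24; the other counts were identical adjusted over the list alone. The 25S control read 3490 and 4179 on the rotenone arrays against 15836 and 17327 after 1.25 µM oligomycin. Of 3025 probe sets past the threshold, 1647 were higher and 1378 lower after rotenone; 1813 passed without rotenone 3 h replicate 1 and 1624 with only the arrays compared in the fit.

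Salicylic acid, a defence hormone, was given at 10 or 100 µM for 3 h. UGT76B1, whose product glucosylates salicylic acid, rose by 5.37 ± 0.28 and 7.08 ± 0.28 (n = 2 at each dose, adjusted p = 1.16e-14 and 2.02e-18). The untreated mean signal of UGT76B1, 17.85, lay under the pseudocount, and the size of its rise depends on it: at 10 µM the difference was 6.91 without a pseudocount and 3.30 with the pseudocount at the median. The glutaredoxin gene GRX480 rose by 2.30 ± 0.27 and 3.83 ± 0.27. These were the 2 measured members of the salicylic acid response list, too few for a list test. Sulfur assimilation rose in 5 of 5 members at 10 µM (median 0.88, adjusted p = 1.16e-07) and 4 of 5 at 100 µM (median 1.66, adjusted p = 7.24e-07), with BGLU28 at 4.94 ± 0.22 and 5.33 ± 0.22 and the ATP sulfurylase gene APS3 at 1.06 ± 0.12 at the lower dose. NDB2 rose by 1.28 ± 0.15 and 1.85 ± 0.15. At 10 µM, 7 of 8 hypoxia response genes fell, adjusted over the list alone as well (median -0.77, adjusted p = 2.18e-05; adjusted p = 0.0969 with an estimated correlation), among them AT4G10270 (WIP4) by 1.12 ± 0.19. At 100 µM, 5 sulfur assimilation genes rose adjusted over the list alone. Of 2493 probe sets past the threshold at 10 µM, 1277 rose and 1216 fell (1243 past it without replicate 1 of that dose, 1476 without replicate 2), and of 4833 at 100 µM, 2091 rose and 2742 fell (3165 without replicate 1 of that dose).

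The difference between the salicylic acid doses was tested directly. At 100 µM transcripts of the heat shock protein genes AT1G53540 (HSP17.6C) and AT2G29500 (HSP17.6B) stood higher by 4.76 ± 0.34 and 3.13 ± 0.27 (n = 2 and 2, adjusted p = 7.56e-11 and 4.40e-09). Of their list, 3 of 4 members were higher (median 2.24, adjusted p = 7.32e-09). All 4 members of xenobiotic detoxification were higher (median 1.75, adjusted p = 2.23e-09), such as UGT73B5 by 1.83 ± 0.20; both counts were identical adjusted over the list alone. AT4G39320 was lower by a log2 difference of -2.24 ± 0.30. Of 1002 probe sets past the threshold, 487 were higher and 515 lower at 100 µM. Without 10 µM replicate 1 or 2 the count was 437 or 453, and without 100 µM replicate 1 or 2 it was 456 or 499.

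The oligomycin doses differed less. AT3G10040 (HRA1) was higher by 1.84 ± 0.38 at 1.25 µM (n = 2 and 2, adjusted p = 0.0115), but this call ended without 0.125 µM replicate 1 (adjusted p = 0.0696) or 2 (adjusted p = 0.0608), without 1.25 µM replicate 2 (adjusted p = 0.243) and with only the arrays compared in the fit (adjusted p = 0.323). AT4G10270 (WIP4) was higher by 1.23 ± 0.22 (adjusted p = 0.00357), a call that ended without 1.25 µM replicate 2 (adjusted p = 0.0625). BGLU28 was lower by a log2 difference of -1.29 ± 0.26 (adjusted p = 0.008) and UGT73B5 by -0.95 ± 0.20 (adjusted p = 0.0156). Both calls ended without 0.125 µM replicate 2 (adjusted p = 0.0849 and 0.151) and without 1.25 µM replicate 1 (adjusted p = 0.0859 and 0.194). With only the arrays compared in the fit these 3 ended as well (adjusted p = 0.103, 0.154 and 0.334). The count past the threshold was 168 (83 higher, 85 lower), with 85 without 0.125 µM replicate 1, 76 without replicate 2 of that dose and 108 without 1.25 µM replicate 2. It was 97 without a filter, 263 with a replicate block, 72 with 3 h arrays alone and 1 with only the arrays compared in the fit.

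Chloramphenicol, an inhibitor of translation on organelle ribosomes, was given at 200 µM for 3 h or 12 h. At 3 h, BGLU28 rose by 3.71 ± 0.22 (n = 2, adjusted p = 1.65e-12) and UGT73B4 by 2.14 ± 0.20. Sulfur assimilation rose in 3 of 5 members (median 0.69, adjusted p = 3.88e-11; 4 adjusted over the list alone), including SIR, the sulfite reductase gene, at 0.58 ± 0.10. Of 8 hypoxia response genes 7 fell, adjusted over the list alone as well, where 1 also rose (median -0.90, adjusted p = 4.16e-09), such as AT5G10040 (HUP9) by 2.63 ± 0.38. Of 67 plastid-encoded and 14 mitochondrially encoded transcripts, 0 passed the test, in either direction, adjusted over the list alone as well; at an unadjusted p under 0.05 limma counted 5 and 0. The plastid list itself passed (median 0.20, adjusted p = 0.00103; adjusted p = 0.742 with an estimated correlation), but not without untreated 3 h replicate 3 (median 0.10, adjusted p = 0.161). The largest of these differences were 0.75 ± 0.24 for rpoC2 (adjusted p = 0.106, or 0.0361 with only the arrays compared in the fit) and 0.23 ± 0.21 for nad1 (adjusted p = 0.712). Of 380 probe sets past the threshold, 250 rose and 130 fell; the count was 190 without chloramphenicol 3 h replicate 1, 180 without replicate 2 and 200 with only the arrays compared in the fit.

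After 12 h of chloramphenicol, AT2G41730 rose by 3.22 ± 0.22 (n = 2 and 2, adjusted p = 6.17e-11) and UGT73B4 by 2.54 ± 0.23. NDB2 and NDB4, of alternative respiration, rose by 1.16 ± 0.17 and 1.00 ± 0.19, which were 2 of the 4 measured members of that list, adjusted over the list alone as well (median 0.63, adjusted p = 0.000787). The mitochondrial dysfunction stimulon also holds NDB2. In it 2 of 5 rose, 3 adjusted over the list alone (median 0.61, adjusted p = 3.46e-05), with AT2G21640 (UPOX) at 1.87 ± 0.22. That list moved further at 12 h than at 3 h (median difference of effects 0.85, adjusted p = 0.000113; 1 of 5 members, 2 adjusted over the list alone), and AT2G21640 by 1.95 ± 0.29. Of 916 probe sets past the threshold, 503 rose and 413 fell; the count was 460 and 428 without untreated 12 h replicates 1 and 2, and 427 and 573 without chloramphenicol 12 h replicates 1 and 2. The effects at both times differed for 115 probe sets (53 up, 62 down): 72 and 57 without chloramphenicol 3 h replicates 1 and 2, 73 and 52 without untreated 12 h replicates 1 and 2, and 42 without chloramphenicol 12 h replicate 1. With quantile normalization 193 differed, and with untreated 3 h arrays 3 and 4 alone 191.

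Norflurazon, an inhibitor of carotenoid synthesis, changed few transcripts by 12 h. AT1G76360 rose by 2.38 ± 0.37 (n = 2 and 2, adjusted p = 0.000434), the largest rise among named genes. The 3 measured genes of carotenoid and tetrapyrrole synthesis and the 4 of photosynthesis did not pass, with 0 rising or falling adjusted over the list alone, LYC (lycopene cyclase) at -0.10 ± 0.12 (adjusted p = 0.866) and LHCB4.1 at 0.12 ± 0.14 (adjusted p = 0.864); at an unadjusted p under 0.05 limma counted 0 in each. Of 163 probe sets past the threshold, 139 rose and 24 fell. The count was 48 and 51 without untreated 12 h replicates 1 and 2, 38 and 53 without norflurazon replicates 1 and 2, 281 with 12 h arrays alone and 407 with only the arrays compared in the fit.

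Cysteine, a sulfur amino acid, was applied for 12 h by the titles, while the protocol text of these arrays names chloramphenicol at 1 mM. The data did not decide between them. Changes given for cysteine here and elsewhere are those of the arrays so titled. UGT73B4 rose by 4.22 ± 0.23 (n = 2 and 2, adjusted p = 1.10e-14), and all 4 members of xenobiotic detoxification rose (median 1.97, adjusted p = 6.14e-06). In the cold response list 5 of 7 rose (median 1.07, adjusted p = 0.000515), with LTI30 at 2.86 ± 0.16 and COR15A at 1.42 ± 0.25. All 3 cell division genes fell (median -0.98, adjusted p = 0.000596), among them AUR2 by 1.07 ± 0.13 and PRL by 0.98 ± 0.13. These counts were identical adjusted over the list alone. EXPA4 fell by 4.89 ± 0.13 and AT4G24780 by 4.58 ± 0.18. Of 5 sulfur assimilation genes 0 passed, adjusted over the list alone as well, with 3 at an unadjusted p under 0.05 in limma; BGLU28 was at 0.55 ± 0.26 (adjusted p = 0.112), a difference that passed with 12 h arrays alone (adjusted p = 0.0386) and with only the arrays compared in the fit (adjusted p = 0.049). Of 3484 probe sets past the threshold, 1648 rose and 1836 fell, with 2274 past it without untreated 12 h replicate 2.

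**Figure D4:**
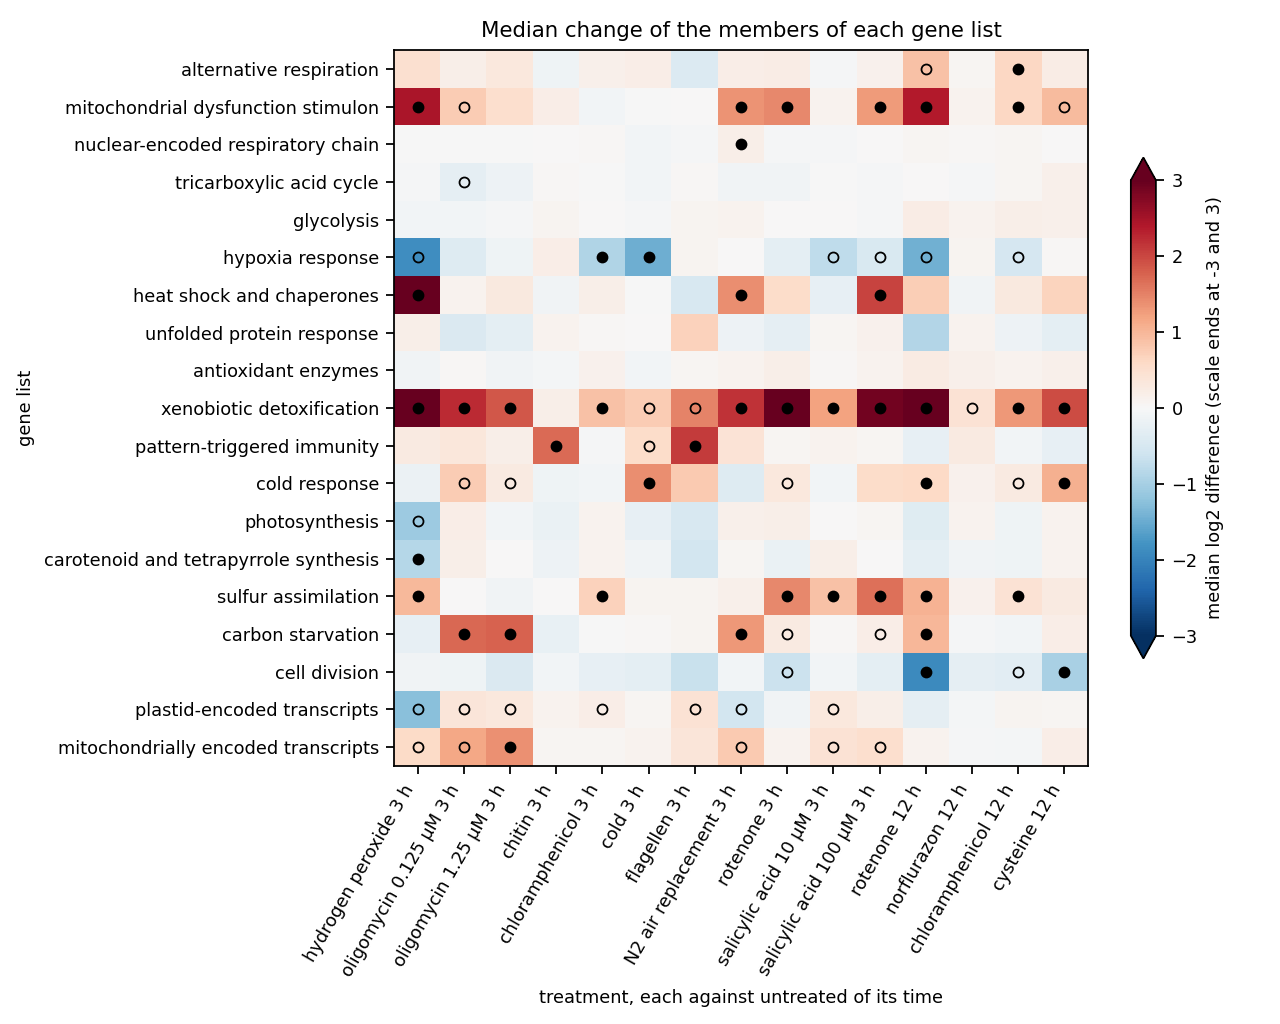
Median log2 difference of each of 19 gene lists (vertical axis) in 15 treatments (horizontal axis), in colour from -3 to 3; filled dots mark lists past the threshold with a preset and an estimated correlation, open dots with the preset alone. Xenobiotic detoxification passed with the preset correlation in 14 of 15 treatments and with an estimated correlation in 11, and its highest median was 4.26.

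Across treatments, UGT73B4 rose in 14 of 15, by up to 5.48 after 12 h of rotenone, and NDB2 rose in 11 of 15, by up to 2.46 after hydrogen peroxide. NDB4 rose in 4 of 15. Transcripts of AT4G01870 and AT4G13180 rose in 15 of 15. PR-1-LIKE fell in 12 of 15. These counts share untreated arrays and so are not independent of each other.

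**Figure D5:**
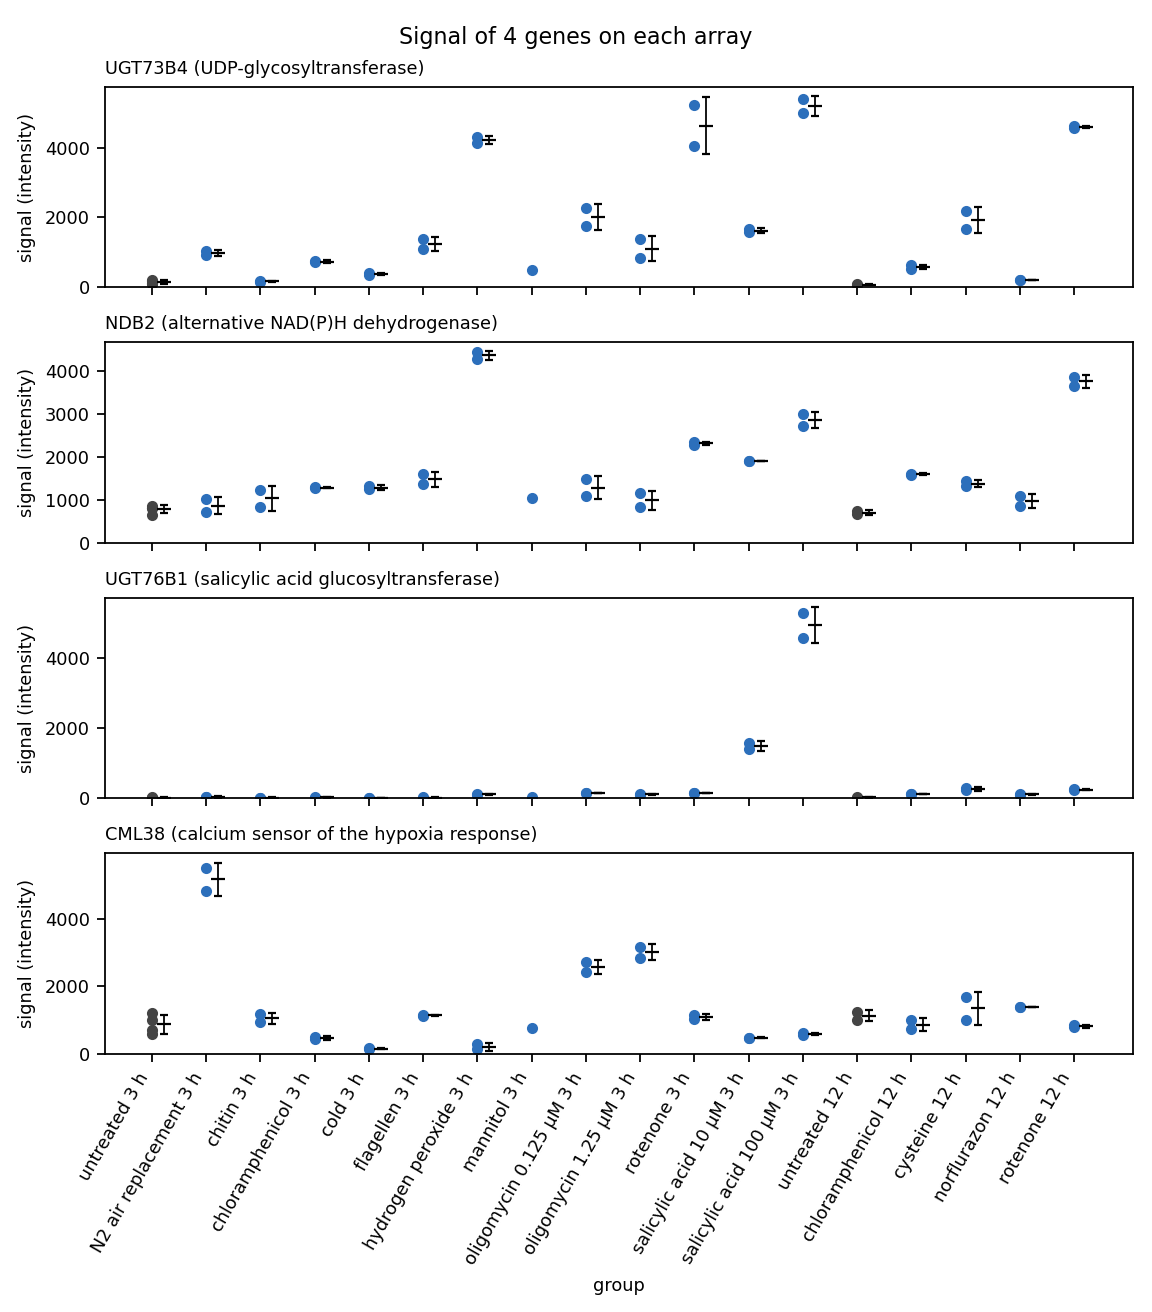
Signal (intensity) of UGT73B4, NDB2, UGT76B1 and CML38 on each array (dots) by group, with the group mean and SD beside them where a group has more than 1 array. UGT76B1 averages 4937 after 100 µM salicylic acid and 17.85 in untreated 3 h cells, and CML38 averages 5182 under N2.

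Untreated cells at 12 h and 3 h were also compared. AT3G45220 was higher by 3.06 ± 0.29 at 12 h (n = 2 and 4, adjusted p = 4.67e-09), and SK19 lower by a log2 difference of -2.57 ± 0.13. Of 67 plastid-encoded transcripts 49 were higher at 12 h, 54 adjusted over the list alone (median 0.95, adjusted p = 3.99e-16; adjusted p = 0.301 with an estimated correlation), such as psbB at 1.93 ± 0.31. In total 2362 probe sets were higher and 1812 lower; the count of 4174 was 2347 and 2280 without untreated 12 h replicates 1 and 2. The dap spike-in control read 1.2 to 3.5 on 12 h arrays and 804 to 1417 on 3 h arrays, so time and array processing cannot be separated here. The 25S control read 9383 and 9745 on these 12 h arrays.

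Mannitol, an osmotic agent, was given at 3% w/v to 1 sample, so the differences have no replicate check and no p-value. IAA20, IAA30 and GH3.3 stood above all 4 untreated arrays, by log2 differences of 4.41, 3.88 and 3.64. The expansin-like genes EXLA3 and EXLA1 stood below them, at -3.05 and -2.91, and GAT1_2.1 at -3.21. In all, 196 probe sets lay above and 507 below all 4 untreated arrays by at least 2-fold, whereas 20 to 53 lay so far from the other 3 when each untreated array was set against them. The total of 703 became 307 with the pseudocount at the median and 1237 without a filter. Medians of xenobiotic detoxification (0.77) and pattern-triggered immunity (0.58) lay at the 99.9 percentile of random lists of equal size and level, and those of plastid-encoded (0.30) and mitochondrially encoded transcripts (0.49) at the 100 percentile. With each untreated array set against the other 3, the highest percentiles of these lists were 99.9, 99.5, 100 and 100. The highest untreated medians were 0.45, 0.38, 0.29 and 0.22. For these lists the percentiles hardly set the mannitol array apart. Its medians lay above those of every untreated array, though barely so for plastid-encoded transcripts. Other lists lay further from the untreated arrays in percentile. The mitochondrial dysfunction stimulon (0.59) lay at the 99.6 percentile and alternative respiration (0.52) at 99.5. Their untreated percentiles were at most 93 and 89.5, with medians of at most 0.16. Carotenoid and tetrapyrrole synthesis (-0.73) lay at 0.77, against untreated percentiles of 18.1 to 99.5. The 25S control read 1488 on the mannitol array against 207 to 497 in untreated cells.

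For 4 groups the labels conflict with the titles. The arrays titled cold and flagellen are described elsewhere as chloramphenicol, the protocol text of norflurazon names rotenone at 100 µM and that of cysteine names chloramphenicol at 1 mM. Cold differed from chloramphenicol at 3 h for 1394 probe sets, with the cold response list higher in 6 of 7 members, adjusted over the list alone as well (median 1.46, adjusted p = 2.24e-12). Flagellen differed from chloramphenicol for 6541, with all 6 immunity genes higher, adjusted over the list alone as well (median 2.24, adjusted p = 3.65e-06). Norflurazon differed from rotenone (40 µM) at 12 h for 5496 and cysteine from chloramphenicol (200 µM) for 1206, counts that include any effect of the differing doses. The first of these counts was 681 and 672 without chloramphenicol 3 h replicates 1 and 2 and 700 without cold replicate 2. The last was 642 and 655 without chloramphenicol 12 h replicates 1 and 2, 430 without cysteine replicate 2 and 792 with only the arrays compared in the fit.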

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

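The tests of conflicting labels were planned before the values were seen; the comparison of counts under differing doses and the tests on organelle transcripts, the dap control and the hypoxia response list were chosen after seeing the results, with their bounds set after the values were known.

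One untreated 3 h array stood far from the other 3 for 11 of 163 named probe sets, by the share of the range taken up by its gap to the nearest of them. Chance sets apart about 1 in 20 groups, which is near this number. Replicate 3 stood apart for AT2G43620 (0.972), PUB22 (0.97), AT1G69890 (0.925), YLS5 (0.91), AT2G44370 (0.844) and AT2G21640 (0.841). Replicate 2 stood apart for AT5G47030 (0.915), SIR (0.865) and atpF (0.832), and replicate 4 for AT1G76600 (0.891) and AT5G17980 (0.851).

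The rotenone effect differed between 12 h and 3 h, by a test of the difference, for 2354 probe sets. Time and array processing cannot be separated in this or in the chloramphenicol difference below. The mitochondrial dysfunction stimulon lay higher at 12 h by a median of 1.31 and carbon starvation by 0.88. Among named genes the difference was positive for AT1G66180 at 3.12, GSTU25 at 3.10, AT2G21640 at 2.71, AT2G18480 at 2.63, AT5G09570 at 1.31, AT3G15450 at 1.25, NDB4 at 1.19, IVD at 1.00 and NDB2 at 0.83. The NDB2 difference missed the threshold without untreated 12 h replicate 2 (0.75, adjusted p = 0.0583). The cell division list lay lower at 12 h by a median of -1.15, with PRL at -1.33 and AUR2 at -1.15. The largest negative differences among named genes were AT4G24780 at -5.70, EXPA4 at -5.27, PR-1-LIKE at -4.84 and AT1G28400 at -4.61.

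The chloramphenicol effect differed between 12 h and 3 h, by the same kind of test, for 115 probe sets, a count that was 42 without chloramphenicol 12 h replicate 1, 52 and 73 without untreated 12 h replicates 2 and 1, and 57 and 72 without chloramphenicol 3 h replicates 2 and 1. The mitochondrial dysfunction stimulon lay higher at 12 h by a median of 0.85, AT2G21640 by 1.95 and LTI30 by 1.82. These calls held with each array left out.

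The other chloramphenicol differences were less stable, and those of AT5G43450 and AT2G19980 involve a group mean under the pseudocount (4.65 and 18.3), so their sizes depend on it. Without chloramphenicol 12 h replicate 1 the calls ended for AT5G43450 (2.2, then 2.04 at adjusted p = 0.105), AT5G17820 (1.90, then 1.59 at 0.237), AT2G19980 (-1.84, then -1.69 at 0.109), BGLU28 (-1.69, then -1.44 at 0.0997), AT1G47655 (-1.61, then -1.41 at 0.103), AT1G03820 (-1.55, then -1.54 at 0.0569) and NDB4 (1.2, then 1.26 at 0.0569). They also ended without chloramphenicol 3 h replicate 1 for AT5G43450 (2.21), AT5G17820 (1.76) and AT1G47655 (-1.53), and without replicate 2 for AT5G43450 (2.18), AT5G17820 (2.05), AT2G19980 (-1.74), BGLU28 (-1.61) and NDB4 (0.97). Without untreated 12 h replicate 1 they ended for AT5G43450 (2.23), AT2G19980 (-1.76) and BGLU28 (-1.49), and without replicate 2 for AT5G43450 (2.17), AT5G17820 (1.57), AT2G19980 (-1.92), AT1G47655 (-1.62) and NDB4 (1.14). Leaving out untreated 3 h replicate 1 or 4 ended AT5G17820 (1.86 and 1.88), and chloramphenicol 12 h replicate 2 ended NDB4 (1.13).

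Among lists, cold response differed between the chloramphenicol times by a median of 0.51, alternative respiration by 0.31 and sulfur assimilation by -0.44. The last pair ended without chloramphenicol 12 h replicate 1 (0.29 and -0.36). Alternative respiration ended also without untreated 12 h replicate 2 (0.21), and sulfur assimilation without untreated 12 h replicate 1 (-0.49). With an estimated correlation none of the 3 passed (adjusted p = 0.0834, 0.0758 and 0.0758).

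The 25S ribosomal RNA control, which no comparison used, read above every untreated array of the same time in 12 groups. At 3 h the means were 16580 and 15450 after 1.25 and 0.125 µM oligomycin, 15580 under N2, 3834 after rotenone, 1544 after hydrogen peroxide, 1488 after mannitol, and 1072 and 875 after 10 and 100 µM salicylic acid. Untreated 3 h arrays read 207 to 497. At 12 h the means were 12380 after rotenone, 11750 after cysteine, 11080 after chloramphenicol and 10390 after norflurazon. Untreated 12 h arrays read 9383 and 9745, so the excess there was small beside that of oligomycin and N2. With 2 arrays per group at 12 h, such an order alone says little.

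In the oligomycin and N2 arrays, high 25S readings came with more mitochondrially encoded transcript. Carry-over of RNA without a poly-A tail would raise the transcripts of both organelles. Plastid-encoded transcripts lay at a median of -0.55 under N2, with 34 of 67 fallen and 0 risen, which argues against that explanation there. The list call itself is weak: it was lost with an estimated correlation (adjusted p = 0.528) and without N2 replicate 1 (-0.28, adjusted p = 0.251), and single untreated arrays lay as far as -0.28 from the other 3. After oligomycin the lower of the medians was 0.33, and 0.22 with a replicate block, so carry-over may explain that part. Untreated replicate 1 lay at 0.29 from the other 3, so the oligomycin value is near the spread of untreated arrays and weighs little. Joint processing with the 12 h arrays is argued against by the lowest dap reading of these arrays, 986, and an effect of treatment on organelle transcripts stays open and untested.

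Genes of the hypoxia response fell after cold, chloramphenicol and other treatments. The list, with 8 measured genes, moved down in 7 of 15 treatments, 2 of them with an estimated correlation as well, and up in 0. A longer list, with 24 measured genes, shares members with it and was chosen after seeing the data. That list moved down in 8 of 15, 7 of them with an estimated correlation as well. It moved up in 3, and in 0 with an estimated correlation. The values below are those of the shorter list. Shared untreated 3 h arrays set high for these genes would be a technical cause. The untreated arrays did differ among themselves on this list. Each set against the other 3, replicates 1, 2, 3 and 4 had list medians of -0.13, -0.51, 0.25 and 0.31. At 12 h, with other untreated arrays, the less negative of the medians for rotenone and chloramphenicol was -0.50, which argues against it as the whole cause, although neither 12 h call held with an estimated correlation (adjusted p = 0.389 and 0.18). The untreated cells could also have been short of oxygen already. Under N2 the list moved by 0.01 with members going both ways. Its median was higher, and the list passed, with untreated 3 h arrays 1 and 2 alone, which a replicate block also leaves as the controls. A shortage of oxygen in the untreated cells thus cannot be told apart from a change brought by the treatments.

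For 4 groups a wrong title was tested, since another label names a different compound. Probe sets past the threshold numbered 1394 between the arrays titled cold and chloramphenicol, 6541 between flagellen and chloramphenicol, 5496 between norflurazon and rotenone, and 1206 between cysteine and chloramphenicol. The first count was 681, 672 and 700 without chloramphenicol 3 h replicate 1, replicate 2 or cold replicate 2, and the last was 642, 655 and 430 without chloramphenicol 12 h replicate 1, replicate 2 or cysteine replicate 2. The counts for cold and flagellen argue against those arrays holding the same chloramphenicol treatment. The protocol texts of norflurazon and cysteine give other doses, 100 µM rotenone against 40 µM and 1 mM chloramphenicol against 200 µM, which the planned bound of 100 probe sets left out of account. Against untreated cells norflurazon had 163 probe sets past the threshold (38 to 407 over all settings) and 40 µM rotenone 6007 (4595 to 6667), which argues against a higher dose of rotenone in the norflurazon arrays. Cysteine had 3484 and 200 µM chloramphenicol 916, and a stronger effect is what a higher dose of chloramphenicol could give. Replicate differences of cysteine and chloramphenicol at 12 h correlated at 0.441, the highest of all pairs of groups. The next among 12 h pairs was 0.215. That correlation does not tell which compound the arrays titled cysteine received. Changes of dose alone gave 1002 probe sets between salicylic acid doses (437 to 499 with an array left out) and 168 between oligomycin doses, so for the cysteine arrays cysteine and 1 mM chloramphenicol cannot be told apart by the count.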

How the results depend on the processing

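Alternatives with untreated 3 h arrays 1 and 2 alone, with arrays 3 and 4 alone, with arrays of 1 time point alone, and with a replicate block among the 12 h arrays were tests chosen after seeing the data; the rest were planned. Where a result changed, the cause was not tested, apart from fewer arrays in a fit. Values as deposited gave identical results. Of 572 gene results, 562 kept their direction and side of the threshold with quantile normalization, 552 without a pseudocount, 550 without a filter, 554 with a replicate block and 545 with only the arrays compared. Of 780 list results, 756 kept theirs with quantile normalization, 729 without a filter, 745 with a replicate block and 652 with an estimated correlation, under which 131 of 259 list calls held. With each array left out, 2945 of 3178 gene results and 4023 of 4200 list results were kept; a lone array left in a group is then assumed to vary like the others. Signals near the pseudocount limit small changes.

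With quantile normalization TPI and the cytosolic ribosomal proteins turned to -0.02 each under N2, the chloramphenicol difference between times had 193 probe sets, and the N2 split moved from 33.8% to 44.7% risen. Without a filter the oligomycin doses differed for 97 and mannitol for 1237 probe sets, and with the pseudocount at the median mannitol for 307. With a replicate block the oligomycin doses differed for 263. Replicate differences of the 12 h groups correlated in all 10 pairs (0.109 to 0.441), and a replicate block among the 12 h arrays kept 156 of 156 gene results and 267 of 270 list results, with none of the printed calls changed and no count moved by more than 1.5 times. With only the arrays compared, counts were 200 for chloramphenicol at 3 h, 1235 for cold, 407 for norflurazon, 1 between oligomycin doses, 1624 for rotenone against oligomycin and 792 for cysteine against chloramphenicol. With untreated 3 h arrays 3 and 4 alone they were 1378 for cold and 191 for the chloramphenicol difference between times. With arrays of 1 time point alone they were 72 between oligomycin doses and 281 for norflurazon.

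Leaving out 1 array at a time gave lowest and highest counts of 834 and 1592 for chitin, 180 and 380 for chloramphenicol at 3 h, 804 and 2316 for cold, and 2424 and 3800 for rotenone at 3 h. For salicylic acid they were 1243 and 2517 at 10 µM, 3165 and 4708 at 100 µM, and 437 and 499 between doses. They were 38 and 53 for norflurazon, 427 and 573 for chloramphenicol at 12 h, 2274 and 2588 for cysteine, and 2280 and 3974 between untreated times. Oligomycin doses gave 76 and 232, rotenone against oligomycin 1813 and 2417, and the chloramphenicol difference between times 42 and 139. Cold against chloramphenicol gave 672 and 952, and cysteine against chloramphenicol 430 and 984.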

Other observations

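The lists and genes named in this part, and the tests on them, were chosen after seeing the data.

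A list with histone genes moved up in 9 of 15 treatments and down in 3, with an estimated correlation as well in 4 and 2. The 4 are oligomycin at both doses, N2 and 3 h of rotenone, the 3 h groups with the highest 25S control means (15450, 16580, 15580 and 3834, against 325 in untreated cells), so a sign of RNA or labelling state moves with the list. The list holds 6 measured histone genes and PRL (MCM7), a gene of the replicative helicase, and the 6 that rose were the histone genes each time. Of these 7 members, 6 rose after 0.125 µM oligomycin (adjusted p = 3.94e-08), 6 rose and 1 fell after 1.25 µM (median 1.36, adjusted p = 1.63e-07), 6 rose under N2 (median 1.07, adjusted p = 2.54e-06) and 6 rose and 1 fell after rotenone (median 1.01, adjusted p = 1.89e-06). The member that fell was PRL, at -0.46 after 1.25 µM oligomycin and -0.63 after rotenone, where the Aurora kinase gene AUR2 also fell, by 0.76. The rotenone effect on this list was lower at 12 h than at 3 h for all 7 members (median difference -1.35, adjusted p = 2.54e-10). At 12 h, 6 fell after cysteine (median -1.04, adjusted p = 5.62e-07) and 4 after chloramphenicol (median -0.48, adjusted p = 2.47e-07). Each of these calls also held with an estimated correlation.

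Cell wall families, 27 measured genes, moved down in 9 of 15 treatments, 5 of them with an estimated correlation as well. They moved up in 1, which did not hold with an estimated correlation. After cysteine 16 fell and 2 rose (median -0.60, adjusted p = 3.64e-08), after 100 µM salicylic acid 16 fell and 3 rose (median -0.64, adjusted p = 5.55e-06), and after 3 h of rotenone 14 fell and 1 rose (median -0.38, adjusted p = 6.98e-06). The UDP-glycosyltransferase family moved up in 12 of 15 treatments, 8 of them with an estimated correlation as well, and the proteasome list passed in 0.

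Among the untreated 3 h arrays, replicates 1 and 2 lay closest, with a root mean square log2 difference of 0.211, and the other pairs lay 0.307 to 0.333 apart.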
